A study of Mus musculus with 16 samples.

How the data were processed

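The measurement was bulk RNA sequencing of cancer cells sorted from mouse pancreatic tumours. Per the series description, KPC pancreatic cancer cells with a 7TCF-eGFP reporter and a construct called Porcn-DMA, whose make-up is not given in the sources used here, were grown as orthotopic tumours, that is, in the pancreas of host mice. The tumours were dissociated and sorted by flow cytometry into 4 populations with 4 libraries each, from 4 mice per group. The groups are called here DN (negative for both reporters), GFP, mScarlet and DP (positive for both). 7TCF-eGFP is a reporter in which TCF binding sites drive green fluorescent protein, so its signal is meant to follow WNT/beta-catenin transcription. The GFP gate is taken as the WNT-responsive population of the design. No label ties the mScarlet gate to a function in words. The description names a WNT-secreting population, and mScarlet is the gate left for it. Per the labels' protocols, RNA came from a micro-scale column kit, and full-length cDNA was made and amplified by PCR for low input before fragmentation and indexing.

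The authors deposited whole-number read counts per gene, keyed by Entrez gene identifier, with no normalization. The submitters' processing notes name the mouse build GRCm38 (mm10), STAR and DESeq2 1.24.0, without the role of each. The read counter, the annotation and any use of strand are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be told apart. This concerns Eno3 (which overlaps Pfn1), Serpind1 (Pi4ka), Bco2 (Il18), Mfsd4a (Elk4), Angptl2 (Ralgps1), Cdc20 (Elovl1), Cdc45 (Ufd1), Eng (Fpgs), Tcf7l1 (Gm15401) and Pltp (Ctsa). Near-identical copies may exchange reads, so Hspa1a and Hspa1b, Eno1, the trypsin and elastase genes and the globin genes are uncertain as single genes. Each file listed 24467 genes, of which 24437 matched a symbol in a RefSeq gene table of assembly GRCm38.p6. The other 30 identifiers held 0.72% to 1.93% of the counts and stayed in the library totals. Of the genes in the lists used below, 9 had no entry in the files.

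Total counts ran from 80647185 to 104273669 per library, and 15476 to 17805 genes had at least 1 count. A count of 3, used as the floor for a gene at 0, was worth 0.0288 to 0.0372 CPM, the unit of counts scaled to a common library total, in a library. Floors and counting intervals (exact binomial) cover counting error only, because the reads carry no molecular identifiers and the cDNA was amplified. No pair of replicates agreed within sampling noise. The lowest chi-square per degree of freedom between replicates was 97.96, so each library counted as 1 replicate.

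The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted to all 16 libraries with the group as the only term, after edgeR's expression filter by group (15963 genes tested) and TMM scaling. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values of single genes below come from this test unless another is named, and log2 fold changes carry their standard error (SE). Group means and SDs are in TMM-scaled CPM with n = 4. Values per library and list scores use TMM factors over all genes and group means use factors over the tested genes, so the scales differ slightly. All 6 comparisons of groups were made, together with the interaction, which tests whether the GFP effect differed between mScarlet-positive and mScarlet-negative cells. Genes called the same way in mScarlet vs DN and in DP vs GFP, and in GFP vs DN and DP vs mScarlet, were counted, since each pair of comparisons shares no library.

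A set of 32 gene lists was fixed before the data were examined, 24 of cancer cell programmes and 8 of markers of other cell types that a sort could hold. Some results of these lists are not reported here. The lists were tested with camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the lists. The same test with an estimated correlation, and fry, were run beside it. Of all list calls in the 6 comparisons, those of the NF-kB list in GFP vs DN and of the mesenchymal list in GFP vs mScarlet held with the estimated correlation, and so did that of the mesenchymal list in DP vs GFP, just under the threshold. The block changed this for some lists, as given with each comparison. A WNT target score, the mean log2(CPM + 1) over 30 WNT/beta-catenin target genes, was compared by a two-sided exact permutation test over the 70 assignments of 4 against 4 libraries, for which 0.0286 is the smallest possible p, with adjustment over 6 comparisons.

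Named genes followed a rule fixed at the same time. It took Axin2, Nkd1, Notum, Lef1, Sp5, Rnf43, Porcn and Wls in every comparison. It took the 8 called genes per direction with the largest fold change, a mean of at least 10 CPM in the higher group and no overlap of the 4 against 4 libraries, passing over gene models without a symbol. It took up to 4 members with the smallest p per list described, and the 4 genes with the smallest p of the interaction if any was called. Any other gene is said to have been chosen after its values were seen.

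The library numbers 1 to 4 recur in each group, but no label says that a number marks a mouse. Whether the numbers pair the libraries was checked by correlating deviations from the group means. All 24 same-numbered pairs correlated positively (0.06 to 0.39), 20 of them above 0.1. In 3 comparisons (GFP vs DN, DP vs DN and DP vs mScarlet) every pair lay above 0.1, and the numbers were taken to pair the libraries there. These 3 comparisons link all 4 groups by number, so a fit with the number as a block is given beside any result whose call it changed or whose count it moved by over 1.5 times.

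The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For mScarlet vs DN it recovered 6% and 40% of them among 15396 genes, with 0 false calls. For GFP vs DN it recovered 20% and 49% among 15391 genes, with 4 false calls, and for DP vs mScarlet 29% and 41% among 15394 genes, with 2. For the interaction it recovered 2% and 27% among 15420 genes, with 1 false call. Most 2-fold changes therefore go undetected at the simulated spread and number of libraries. The simulation gave every group the same spread per gene and kept the libraries independent. Unchanged genes also had the same mean in every group. Each comparison had 1 draw with changed genes of its own. Differences in recovery between the comparisons of 2 groups may therefore reflect the draw. In each draw the hypoxia and glycolysis list was also lowered 2-fold, and its genes are left out of these rates and of the false calls. In the data the GFP replicates differed most, with a chi-square per degree of freedom of up to 1700, against at most 465.4 in DN. The recovery given for GFP vs DN may therefore not carry over. Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, no filter and a stricter filter (10 CPM in 4 libraries), the 8 libraries of a comparison alone, the block, the number of genes detected as a covariate, other pseudocounts, and leaving out each library in turn. After the data were seen, a fit without GFP libraries 1 and 4 was added, because these held the highest macrophage and the highest acinar and fibroblast marker scores.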

Results

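Gene expression was measured in 16 libraries of sorted mouse pancreatic ductal adenocarcinoma (PDAC) cells, 4 each of the DN, GFP, mScarlet and DP populations. KPC cells are a mouse PDAC line. Total counts per library ran from 88707082 to 104273669 in DN, 82118426 to 100358451 in GFP, 80728607 to 92937247 in mScarlet and 80647185 to 87909931 in DP. The comparisons address which transcripts accompany the GFP reporter of the WNT response and the mScarlet gate, which no label ties to WNT secretion.

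Porcn, which encodes the acyltransferase that lipidates WNT proteins for secretion, had its highest mean in the mScarlet libraries. Its level was 61.5 ± 15.3 CPM in mScarlet, 44.6 ± 7.82 in DP, 29.4 ± 7.9 in GFP and 28 ± 4.47 in DN (SD, n = 4). The gene (Entrez 53627) lies on chromosome X from 8193846 to 8206548 in GRCm38. Porcn was called higher in mScarlet than DN (log2 fold change 1.14, SE 0.23, edgeR adjusted p = 0.0262) and lower in GFP than mScarlet (log2 fold change -1.07, SE 0.23, edgeR adjusted p = 0.0364). DP vs DN (log2 fold change 0.67, SE 0.23, edgeR adjusted p = 0.145), DP vs GFP (0.6, SE 0.23, edgeR adjusted p = 0.202) and DP vs mScarlet (-0.46, SE 0.23, edgeR adjusted p = 1) missed the threshold, and DP library 1, at 51.8 CPM, lay above mScarlet library 4, at 39.5 CPM. For Porcn, mScarlet vs DN, the edgeR adjusted p missed it without DN library 1, 2 or 4 (0.0889, 0.0776 and 0.0976) and without mScarlet library 1, 2 or 3 (0.114, 0.101 and 0.079). For Porcn, GFP vs mScarlet, it missed it without GFP library 1 or 4 (0.0717 and 0.0668), without both (0.314), without mScarlet library 1, 2 or 3 (0.121, 0.113 and 0.0978), without DP library 2 (0.0537), in a fit of the 8 libraries alone (0.154) and with limma voom (0.0515). Counts per gene do not tell reads of the endogenous gene from reads of any Porcn sequence in the construct called Porcn-DMA. Wls, the carrier of lipidated WNT proteins, was at 75.8 ± 17.7 CPM in DN and 78.9 ± 17.5 in mScarlet (edgeR adjusted p = 0.951). No comparison called any of the other fixed genes. Rnf43, a WNT feedback inhibitor, was at 4.09 ± 1.6 CPM in DN, 6.8 ± 4.96 in GFP, 9.76 ± 4.28 in mScarlet and 12 ± 6.41 in DP. Several feedback targets were near the detection limit. Axin2 had 272 counts over the 16 libraries, with 0 in 6 of them, and Lef1 had 266. Notum had 71 counts, 62 of them in mScarlet library 3, and Sp5 had 2. Nkd1 had 4637 counts, of which 2759 came from GFP library 4.

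The WNT target score was higher in GFP than in the other populations. It was 2.29 ± 0.16 in GFP, 1.96 ± 0.12 in DN, 1.86 ± 0.07 in mScarlet and 1.89 ± 0.04 in DP (SD, n = 4). The differences were 0.329 for GFP vs DN, 0.43 for GFP vs mScarlet and -0.396 for DP vs GFP, each with the 4 libraries of one group above the 4 of the other (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0571, which missed 0.05). The differences of DP from DN (-0.067, exact permutation adjusted p = 0.4457) and from mScarlet (0.035, exact permutation adjusted p = 0.4571) and of mScarlet from DN (-0.101, exact permutation adjusted p = 0.3429) missed the threshold. With the numbers taken as pairs no difference can pass, since 0.125 is then the smallest possible p, and the exact permutation p was 0.125 for the first 3 (adjusted p = 0.25). DP cells also passed the GFP gate. The direction rested on members of low abundance. With only members at 5 CPM or more, the differences turned to -0.06 for GFP vs DN, -0.036 for GFP vs mScarlet, 0.071 for DP vs GFP and 0.011 for DP vs DN.

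**Figure D1:**
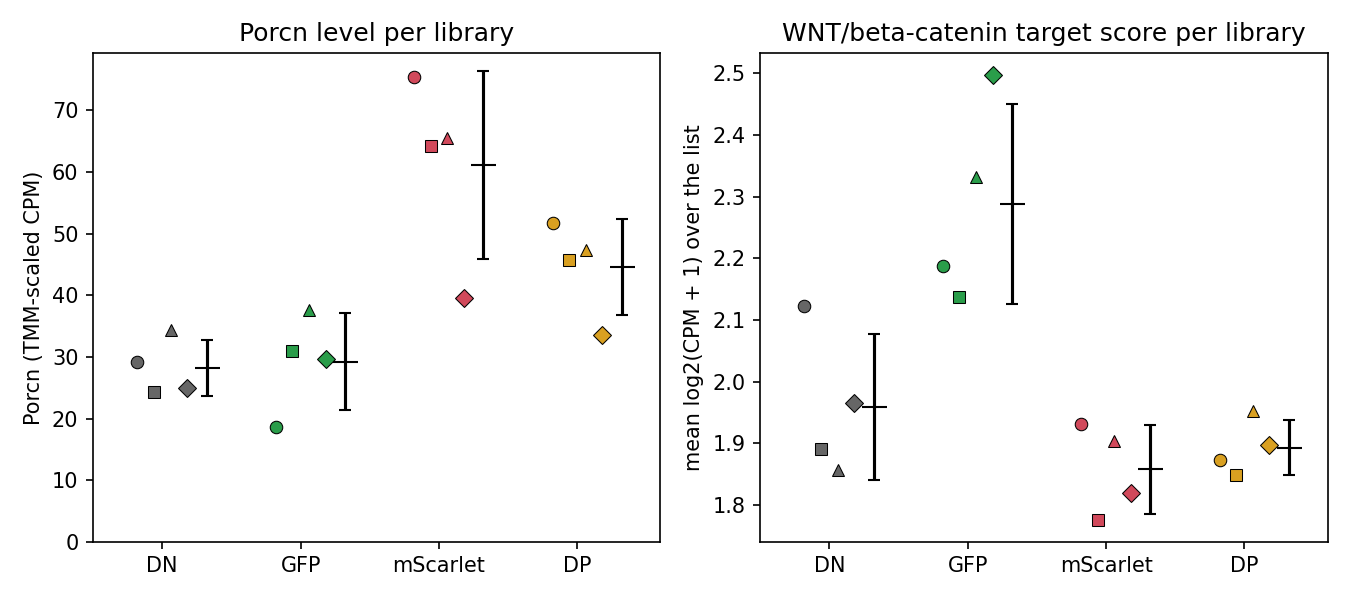
Porcn level in TMM-scaled CPM (left) and WNT/beta-catenin target score as mean log2(CPM + 1) (right) in each of the 16 libraries. Each point is a library, its shape gives the library number, and bars give the mean and SD (n = 4). The lowest mScarlet library, at 39.5 CPM, lay above the highest DN library, at 34.3 CPM.

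Markers of other cell types varied among the libraries. Macrophage markers had a mean score of 7.52 ± 1.83 in GFP and 7.4 ± 0.81 in DP, and of 5.82 ± 1.22 in DN and 5.58 ± 0.86 in mScarlet (SD, n = 4). Fibroblast markers were at 4.4 ± 1.61 in GFP, 2.9 ± 1.07 in DN, 2.01 ± 0.69 in DP and 1.41 ± 0.29 in mScarlet. Acinar markers, digestive enzymes of the exocrine pancreas, were at 6.78 ± 2.54 in GFP, with 10.24 in GFP library 4, and at 4.03 ± 1.27 in DN, 3.67 ± 1.81 in mScarlet and 2.59 ± 0.83 in DP. Erythroid markers reached 8.4 in GFP library 1.

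**Figure D2:**
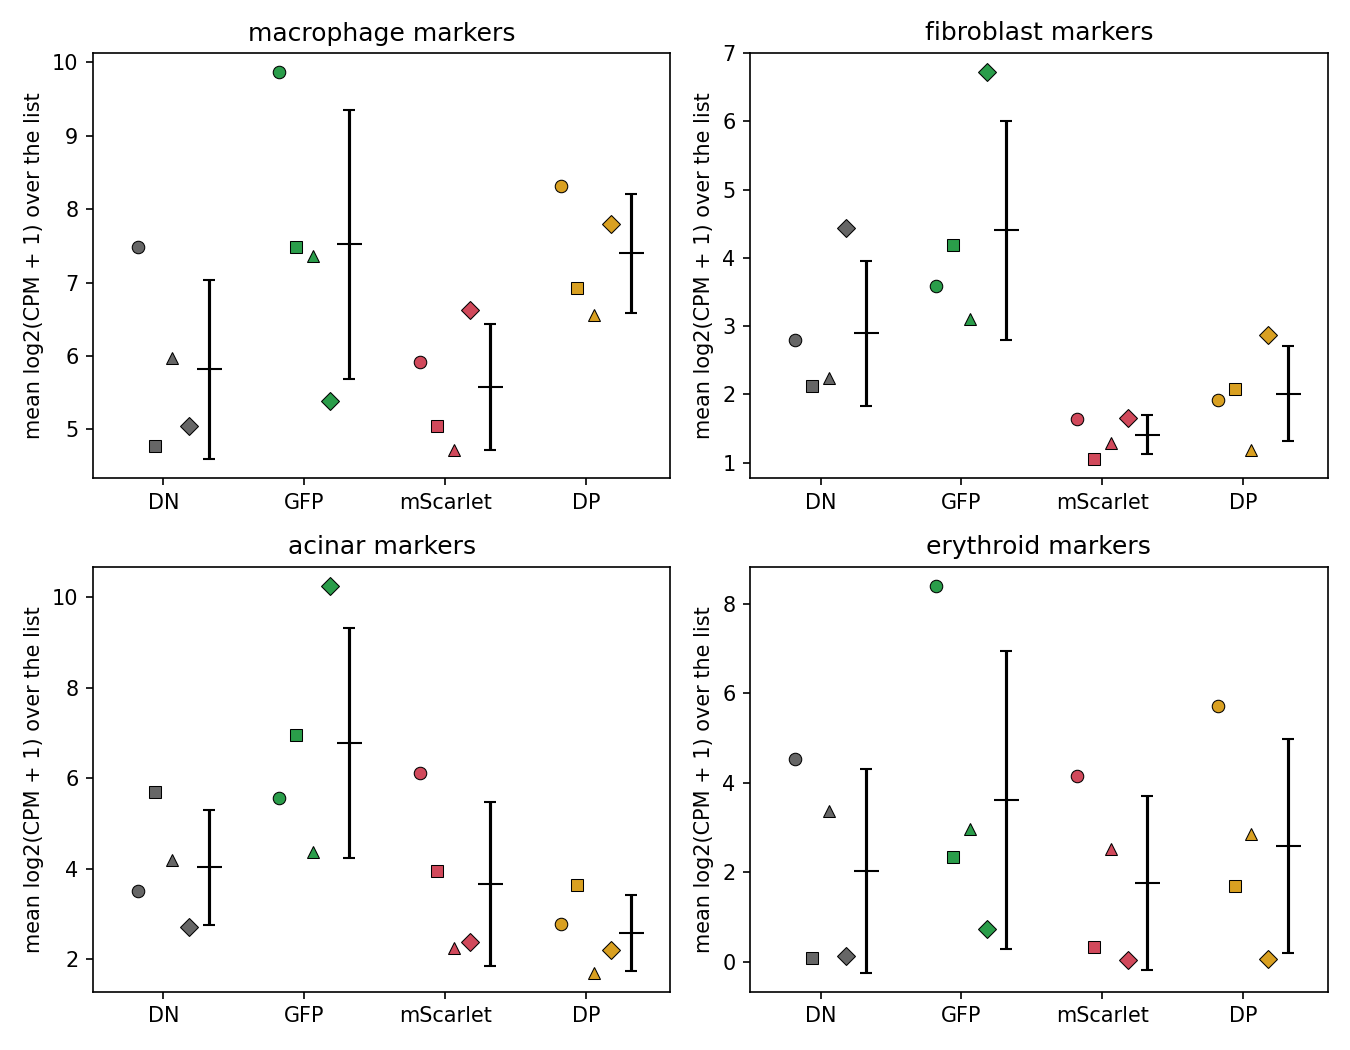
Scores of macrophage, fibroblast, acinar and erythroid markers, as mean log2(CPM + 1) over each list, in the 16 libraries. Points are libraries with the shape giving the library number, and bars give the mean and SD (n = 4). Fibroblast markers reached 6.72 in GFP library 4 and no more than 1.65 in any mScarlet library.

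GFP vs DN asked which genes differ in cells of the GFP gate without mScarlet. Lists of inflammatory, heat shock and WNT target genes were higher in GFP, but no single gene passed the main test. With the library number as a block 11 genes did. The inflammatory list held with an estimated correlation (camera adjusted p = 0.049) but not with the block as well (0.067), and the heat shock and WNT target lists did not (0.23 and 0.17). Hspa1a, a heat shock chaperone on chromosome 17 (34969359 to 34972156), was at 169 ± 115 CPM in GFP and 29.2 ± 6.83 in DN (log2 fold change 2.54, SE 0.41, edgeR adjusted p = 0.138). Il6, an inflammatory cytokine, was at 16.6 ± 15.6 and 2.17 ± 1.33 CPM (log2 fold change 2.94, SE 0.85, edgeR adjusted p = 0.37). It was at 31.1 and 28.9 CPM in GFP libraries 1 and 4, but at 3.92 and 2.39 in libraries 2 and 3, where DN reached 3.49. Among WNT targets, Tnfrsf19 had 1184 counts in GFP and 0 in DN, at least 441-fold higher against a floor of 3 counts over the group (247-fold without GFP library 4), and Lgr5, a WNT-responsive receptor, had 285 and 0, at least 106-fold higher (67.1-fold without GFP library 1). Their edgeR adjusted p-values were 0.367 and 0.357.

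As lists, 13 of 32 were called in GFP vs DN. The NF-kB and inflammatory list rose (19 of 22 members positive, median log2 fold change 0.43, camera adjusted p = 1.1e-06; adjusted p = 0.049 with an estimated correlation). Of its members, 3 were called higher when adjusted over the list alone and 0 over all genes, and Cxcl1 and Ccl2, both chemokines, had log2 fold changes of 1.72 (SE 0.46) and 2.69 (SE 0.83). Both were highest in GFP libraries 1 and 4 (164 and 307 CPM for Cxcl1, 117 and 75.4 for Ccl2). In GFP libraries 2 and 3 they reached at most 82.9 and 19.3 CPM. The score of the whole list did not overlap, at 6.49 to 6.91 in GFP and 5.84 to 6.23 in DN. Immediate-early and heat shock genes rose (19 of 20 positive, median 0.58, camera adjusted p = 5.4e-09; adjusted p = 0.23 with an estimated correlation), 4 of them adjusted over the list alone. WNT/beta-catenin targets rose (16 of 21 positive, median 0.53, camera adjusted p = 0.014; adjusted p = 0.17 with an estimated correlation), with 2 called higher adjusted over the list alone. Secreted WNT inhibitors rose (6 of 6 positive, camera adjusted p = 0.015; adjusted p = 0.42 with an estimated correlation), with Sfrp4 at 48.6 ± 88.1 CPM in GFP and 4.39 ± 8.2 in DN (not called), and so did mesenchymal genes (12 of 18 positive, camera adjusted p = 0.022; adjusted p = 0.39 with an estimated correlation). Lipid and sterol synthesis genes fell (17 of 20 negative, median -0.31, camera adjusted p = 0.00095; adjusted p = 0.49 with an estimated correlation). G2/M phase (16 of 22 negative, median -0.28) and DNA replication genes (17 of 20 negative, median -0.22) fell, each with a camera adjusted p of 0.014 and an adjusted p of 0.62 with an estimated correlation, as did MYC and ribosome biogenesis genes (16 of 20 negative, camera adjusted p = 0.015; adjusted p = 0.39 with an estimated correlation). Markers of other cells moved with them. Macrophage (20 of 20 positive, median 2.57, camera adjusted p = 5.4e-09), fibroblast (20 of 20, median 2.19, camera adjusted p = 1e-08) and acinar markers (21 of 21, median 4.36, camera adjusted p = 2e-12) rose, and lymphocyte markers fell (11 of 16 negative, median -0.98, camera adjusted p = 0.014). With an estimated correlation their adjusted p-values were 0.42, 0.39, 0.39 and 0.51, and 20 acinar markers were called higher adjusted over the list alone and 0 over all genes. With the block, camera also called hypoxia and glycolysis genes lower (16 of 20 negative, adjusted p = 0.022) and epithelial genes (16 of 21 positive, adjusted p = 0.034) and erythroid markers (6 of 6 positive, adjusted p = 1.8e-08) higher, with adjusted p = 0.53, 0.54 and 0.067 at an estimated correlation. The erythroid score differed by 3.86 and 2.25 for numbers 1 and 2 and by -0.4 and 0.61 for numbers 3 and 4. Apoe, abundant in macrophages, was at 4840 ± 4980 CPM in GFP and 625 ± 635 in DN.

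edgeR called 0 genes in GFP vs DN, with 1551 at an unadjusted p under 0.05, while DESeq2 called 245, limma voom with quality weights 2, and the fit without GFP library 2 also 2. With the library number as a block 11 genes were called, 10 higher and 1 lower, among them Hspa1a (block adjusted p = 0.0262) and Il6 (block adjusted p = 0.0364), and, chosen after their values were seen, Pltp (0.00139), Igf1 (0.0262), Ccl7 (0.0305) and Cbr2 (0.0359). Pltp and Cbr2 were highest in GFP library 1 (380 and 180 CPM), which had the highest macrophage score. Igf1 and Ccl7 were highest in GFP library 4 (54.6 and 249 CPM), which had the highest fibroblast score. Whether RNA of other cell types accounts for these calls was not tested.

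mScarlet vs DN asked which genes differ in mScarlet cells without GFP. The list of classical PDAC genes was higher in mScarlet, and those of glycolysis and the cell cycle were lower. None of these list calls held with an estimated correlation (camera adjusted p = 0.11 for classical PDAC, 0.085 for glycolysis, 0.17 for G2/M phase and 0.23 for DNA replication). The trefoil factor Tff1, a mucosal peptide (chromosome 17, 31161395 to 31165060), was at 131 ± 86.4 CPM in mScarlet and 16.8 ± 8.65 in DN (log2 fold change 2.96, SE 0.58, edgeR adjusted p = 0.0261). Tff3 (log2 fold change 3.73), Clca1 (3.24), the sodium-proton exchanger Slc9a4 (3.19), Ces2b (3.03), Sult1b1 (2.91), Lypd8 (2.9) and the intestinal alkaline phosphatase Alpi (2.64) completed the 8 largest increases. Lypd8 reached 173 CPM in mScarlet library 1 and no more than 47.9 in the others. Genes lower in mScarlet included Eno3, an enolase (chromosome 11, 70653125 to 70662513), at 11.2 ± 2.78 against 84.1 ± 32.2 CPM (log2 fold change -2.91, SE 0.3, edgeR adjusted p = 0.000271). The matrix protease Mmp10 (-4.96), the kinase Rps6ka2 (-3.13), Ank (-3.07), Serpind1 (-3), Smtn (-2.65), R3hdml (-2.56) and Arap3 (-2.47) were the other 7. Over 26 alternative settings the calls of Tff3 and Mmp10 were kept in 12, that of Serpind1 in 14, that of Slc9a4 in 25 and that of Eno3 in 26.

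Of the lists, 14 were called in mScarlet vs DN. Classical PDAC genes rose (19 of 22 positive, median 0.88, camera adjusted p = 2.6e-08; adjusted p = 0.11 with an estimated correlation). Of these 6 were called over all genes and 10 adjusted over the list alone, including the secretory chaperone Agr2 (45.8 ± 14.2 against 11.3 ± 3.84 CPM), Tff2 (1290 ± 550 against 360 ± 99) and cathepsin E, Ctse (1240 ± 93.4 against 550 ± 113). Hypoxia and glycolysis genes fell (19 of 20 negative, median -0.93, camera adjusted p = 1.7e-15; adjusted p = 0.085 with an estimated correlation), 8 called over all genes and 14 adjusted over the list alone. Lactate dehydrogenase Ldha was at 2620 ± 224 CPM in mScarlet and 5090 ± 1160 in DN (log2 fold change -0.96, SE 0.16, edgeR adjusted p = 0.013), and the glycolytic genes Eno1 (-0.99) and Tpi1 (-0.93) and the kinase Pdk1 (-1.18) were also called. G2/M phase genes fell (22 of 22 negative, median -1.16, camera adjusted p = 7.3e-12; adjusted p = 0.17 with an estimated correlation), with Cdc20 (-1.52), Cenpa (-1.8) and Plk1 (-1.36), all mitotic, called. DNA replication genes fell (20 of 20 negative, median -0.68, camera adjusted p = 4.1e-10; adjusted p = 0.23 with an estimated correlation), 0 called over all genes and 10 adjusted over the list alone. MYC and ribosome biogenesis genes fell (18 of 20 negative, camera adjusted p = 2.8e-06; adjusted p = 0.082 with an estimated correlation), with the spermidine synthase Srm called (-0.99). Mesenchymal genes fell (16 of 18 negative, median -1.41, camera adjusted p = 2.9e-05; adjusted p = 0.082 with an estimated correlation), with the matrix protein Tnc (6 counts in mScarlet, 1535 in DN) and S100a4 (-2.02) called. Epithelial genes rose (17 of 21 positive, camera adjusted p = 0.00033; adjusted p = 0.25 with an estimated correlation), as did MHC class I (14 of 15 positive, camera adjusted p = 0.00024; adjusted p = 0.25 with an estimated correlation), with H2-T23 called (0.77), and interferon response genes (16 of 22 positive, camera adjusted p = 0.017; adjusted p = 0.52 with an estimated correlation). WNT ligands fell (10 of 12 negative, camera adjusted p = 0.012; adjusted p = 0.11 with an estimated correlation), with Wnt10a at a log2 fold change of -1.2 (edgeR adjusted p = 0.0644, and 0.00194 with the block) and Wnt4 at 0.78 (edgeR adjusted p = 0.182). Secreted WNT inhibitors fell (6 of 6 negative, camera adjusted p = 0.039; adjusted p = 0.49 with an estimated correlation), Igfbp4 being called (-1.19), and lipid and sterol synthesis genes fell (14 of 20 negative, camera adjusted p = 0.016; adjusted p = 0.59 with an estimated correlation). Fibroblast markers fell beside them (19 of 20 negative, median -3.24, camera adjusted p = 0.00033; adjusted p = 0.52 with an estimated correlation), with Pdgfrb called (-6.26), and lymphocyte markers fell (14 of 16 negative, camera adjusted p = 0.0077; adjusted p = 0.49 with an estimated correlation).

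In all, 188 genes were called in mScarlet vs DN, 77 higher and 111 lower, and 865 with the library number as a block, 402 higher and 463 lower, which included all 188. With the block, camera also called endothelial markers lower (13 of 14 negative, adjusted p = 0.011; 0.26 with an estimated correlation). Of the lists called, mesenchymal genes held with the block and an estimated correlation (camera adjusted p = 0.024). The count was 17 without DN library 1, 92 without DN 2, 56 without DN 4, 23, 48, 34 and 312 without mScarlet 1, 2, 3 and 4, 362 and 302 without GFP 1 and 4, 118 without DP 3, and 580 without GFP libraries 1 and 4 together; 9 lists were called without mScarlet 4.

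**Figure D3:**
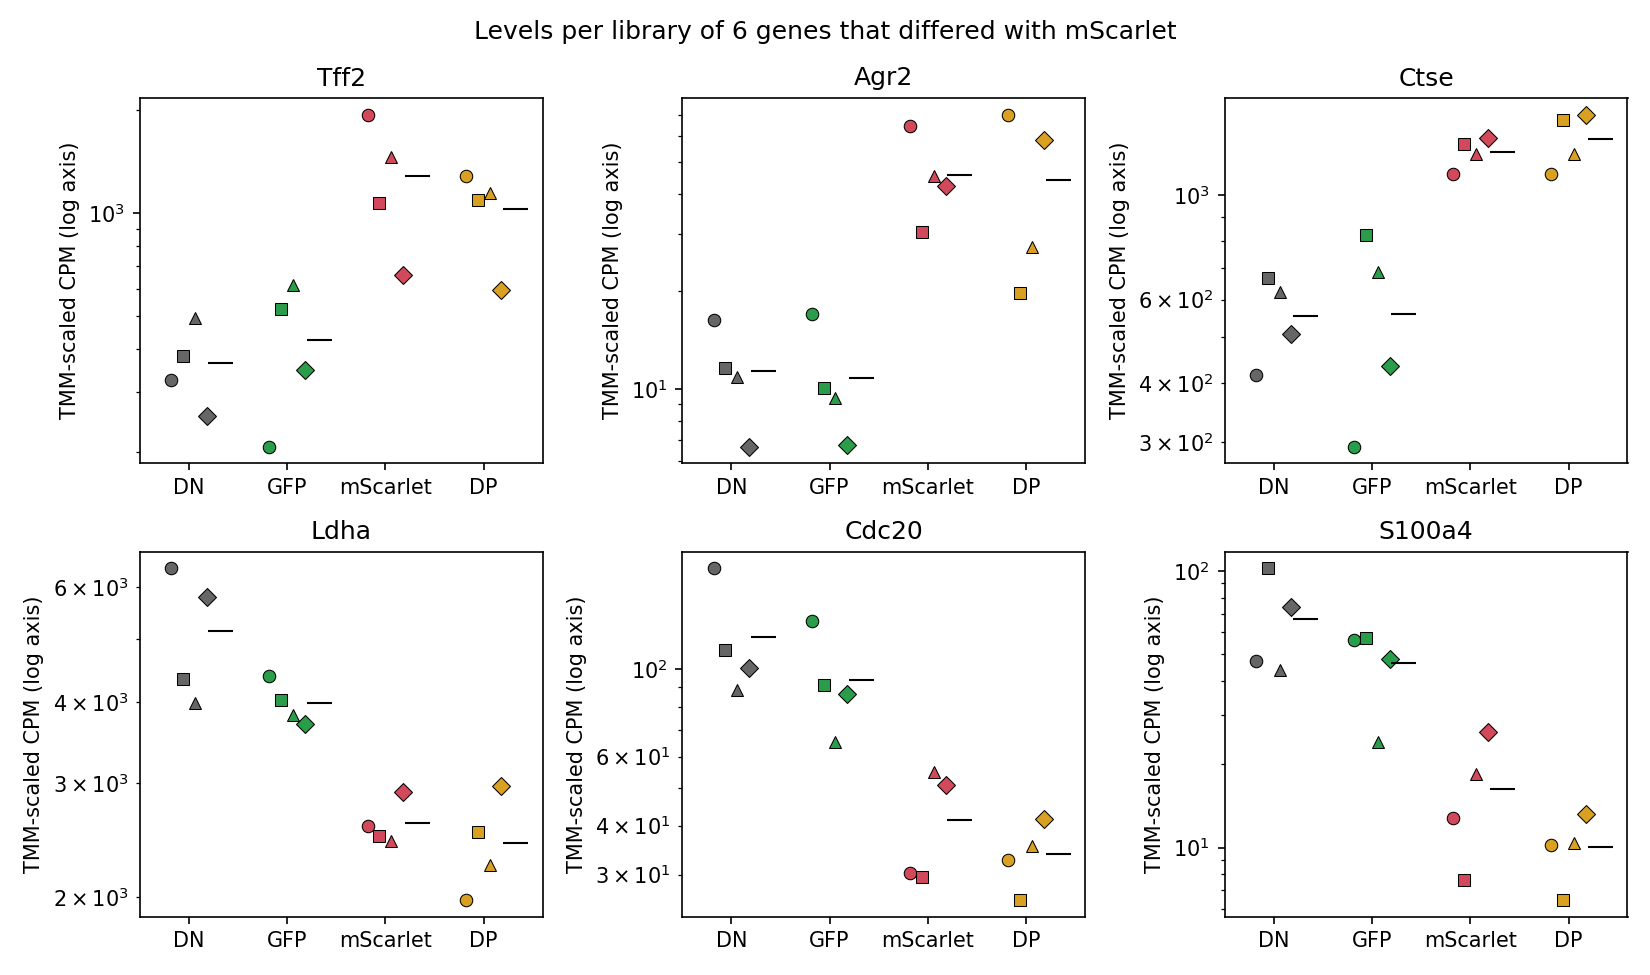
Levels of Tff2, Agr2, Ctse, Ldha, Cdc20 and S100a4 in each of the 16 libraries, in TMM-scaled CPM on a log axis. Points are libraries with the shape giving the library number, and the short line is the group mean (n = 4). Ctse ranged from 1110 to 1320 CPM in mScarlet and from 415 to 668 in DN.

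DP vs DN compared cells positive for both reporters with cells negative for both. Higher in DP were Clca1 (log2 fold change 3.76), Slc9a4 (3.47), Tff3 (3.38), Sult1b1 (3.07), Ces2b (2.96), Lypd8 (2.96), Alpi (2.68) and Tff1 (2.61). Slc9a4 (chromosome 1, 40579986 to 40630731) was at 34.4 ± 17.6 CPM in DP and 3.1 ± 2.33 in DN (SE 0.52, edgeR adjusted p = 0.00392). Lower in DP were the granzyme Gzme (-4.92), Mmp10 (-4.71), Rps6ka2 (-4.2), the R-spondin receptor Lgr6 (-3.8), Eno3 (-3.55), Apoa1 (-3.38), Smtn (-3.35) and Serpind1 (-3.34). Eno3 was at 7.19 ± 1.47 against 84.1 ± 32.2 CPM (SE 0.31, edgeR adjusted p = 5.91e-05). Over 26 alternative settings the call of Mmp10 was kept in 15, that of Tff3 in 16, and those of Slc9a4 and Eno3 in 26. That of Apoa1 was kept in 13 of 25.

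Of the lists, 15 were called in DP vs DN. G2/M phase genes fell (22 of 22 negative, median -1.63, camera adjusted p = 2.7e-14; adjusted p = 0.18 with an estimated correlation), 11 called over all genes and 14 adjusted over the list alone, with Cdc20 at 33.8 ± 6.55 against 120 ± 40.1 CPM. DNA replication genes fell (20 of 20 negative, median -0.87, camera adjusted p = 7.8e-13; adjusted p = 0.18 with an estimated correlation), 7 called over all genes and 15 adjusted over the list alone, among them the helicase subunit Mcm5 (-1.3) and Uhrf1 (-1.67). Hypoxia and glycolysis genes fell (18 of 20 negative, median -0.95, camera adjusted p = 3.2e-14; adjusted p = 0.17 with an estimated correlation), 8 called, with Ldha at -1.07 (SE 0.16) and Gpi1 at -0.78 (SE 0.15). MYC and ribosome biogenesis genes fell (19 of 20 negative, camera adjusted p = 9.4e-07; adjusted p = 0.12 with an estimated correlation). Classical PDAC genes rose (19 of 22 positive, median 0.86, camera adjusted p = 9.4e-07; adjusted p = 0.18 with an estimated correlation), 6 called over all genes and 9 adjusted over the list alone, with Ctse at 1.25 and the keratin Krt20 at 1.03. Mesenchymal genes fell (14 of 18 negative, camera adjusted p = 0.0056; adjusted p = 0.18 with an estimated correlation), with S100a4 (-2.72) and the lysyl oxidase Loxl2 (-2.32) called. Lipid and sterol synthesis genes fell (15 of 20 negative, camera adjusted p = 0.0039; adjusted p = 0.49 with an estimated correlation). Epithelial (17 of 21 positive), MHC class I (14 of 15), interferon response (17 of 22), NF-kB (17 of 22) and immediate-early and heat shock genes (17 of 20) rose, with camera adjusted p-values of 0.0022, 0.0039, 0.011, 0.023 and 0.018. Their adjusted p-values with an estimated correlation were 0.35, 0.38, 0.49, 0.24 and 0.49. Single WNT genes were called lower, Apcdd1, a WNT inhibitor and target, at -2.89 (SE 0.6, edgeR adjusted p = 0.0188), Wnt10a at -1.32 (SE 0.3, edgeR adjusted p = 0.0299) and Igfbp4 at -1.39 (SE 0.27, edgeR adjusted p = 0.013). Other WNT targets and ligands went both ways without being called. Lgr5 (61 counts in DP and 0 in DN) and Wnt4 (0.67) were higher, and Ccnd1 (-0.59) and Wnt7b (-0.4) were lower. The WNT ligand and secreted WNT inhibitor lists missed the threshold (camera adjusted p = 0.058 and 0.066) and passed it with the block, both lower (camera adjusted p = 0.021 and 0.0021; 0.26 and 0.16 with an estimated correlation). Macrophage markers rose beside these (19 of 20 positive, median 1.46, camera adjusted p = 5.1e-06), while fibroblast (19 of 20 negative, median -1.92, camera adjusted p = 0.026) and lymphocyte markers (12 of 16 negative, camera adjusted p = 0.011) fell. With an estimated correlation their adjusted p-values were 0.49, 0.62 and 0.49.

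In all, 371 genes were called in DP vs DN, 98 higher and 273 lower, and 1017 with the library number as a block, 394 higher and 623 lower, which included 370 of the 371. The count was 105, 221 and 169 without DN libraries 1, 2 and 4, 119, 158 and 159 without DP 1, 2 and 3, and 761 without GFP libraries 1 and 4.

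GFP vs mScarlet compared the populations that each carry one reporter. The lists of mesenchymal genes and of fibroblast markers were higher in GFP. The mesenchymal list held with an estimated correlation (camera adjusted p = 0.031), and the fibroblast list did not (0.17). The fibroblast score was also higher in GFP (4.4 ± 1.61, against 1.41 ± 0.29 in mScarlet). Whether RNA of fibroblasts or other cell types moved the mesenchymal list was not tested in any comparison. Tnc, a matrix glycoprotein (chromosome 4, 63959785 to 64047015), was at 12.4 ± 5.22 CPM in GFP and had 6 counts in all mScarlet libraries (log2 fold change 9.41, SE 1.04, edgeR adjusted p = 0.00182). The receptors Fgfr1 (8.28) and Pdgfrb (8.26), Slco2b1 (8.67) and Cyp1b1 (9.17) were also higher. Crocc2, Ssc5d and the chemokine Ccl19 had 1, 3 and 2 counts in mScarlet, with ratios of 4560 (95% counting interval 818 to 180000), 2530 (866 to 12300) and 2480 (687 to 20500). GFP library 4 held most of the reads of these 3, and without it the ratios were 645, 489 and 114. It also held most of the Cyp1b1 reads, at 44.3 CPM against at most 1.86 in the other GFP libraries, and GFP library 1 most of the Slco2b1 reads, at 66.4 CPM against at most 9.97. Lower in GFP were Tspan1 (-2.55), Tff1 (-2.49), Agr2 (-2.07), Ces2b (-2.04), Fam3b (-1.87), the membrane protease Mmp15 (-1.67), Prap1 (-1.67) and Cyp3a13 (-1.61). Prap1 (chromosome 7, 140093396 to 140097203) was at 98.9 ± 37.8 CPM in GFP and 314 ± 89.8 in mScarlet (SE 0.28, edgeR adjusted p = 0.0172). The call of Tff1 was kept in 10 of 26 alternative settings, that of Slco2b1 in 10 of 25, that of Cyp1b1 in 11 of 25, that of Prap1 in 22 of 26 and that of Tnc in 25 of 25.

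Of the lists, 17 were called in GFP vs mScarlet. Mesenchymal genes rose (16 of 18 positive, median 2.33, camera adjusted p = 1.2e-07; adjusted p = 0.031 with an estimated correlation), 6 called over all genes and 12 adjusted over the list alone, with fibronectin, Fn1 (2.29), and the integrin Itga5 (1.27). Classical PDAC genes fell (21 of 22 negative, median -0.83, camera adjusted p = 2.9e-09; adjusted p = 0.12 with an estimated correlation), 6 called over all genes, including Krt20 (-1.13), Ctse (-1.14) and Tff2 (-1.6). Hypoxia and glycolysis genes rose (19 of 20 positive, median 0.75, camera adjusted p = 1.4e-10; adjusted p = 0.12 with an estimated correlation), with Eno1 (0.83), Gpi1 (0.7) and P4ha2 (1.67) called. G2/M phase (21 of 22 positive, median 1.11), DNA replication (20 of 20, median 0.48) and MYC and ribosome biogenesis genes (17 of 20, median 0.23) rose, with camera adjusted p-values of 1.6e-06, 1e-04 and 0.018. Their adjusted p-values with an estimated correlation were 0.27, 0.35 and 0.27. Immediate-early and heat shock genes (18 of 20 positive, camera adjusted p = 0.00014; adjusted p = 0.27 with an estimated correlation) and NF-kB genes (17 of 22, camera adjusted p = 0.017; adjusted p = 0.22 with an estimated correlation) rose, with Hspa1a (2.79), Il6 (4.91) and Cxcl1 (2.11) called. WNT/beta-catenin targets (15 of 21 positive, median 1.16), WNT ligands (11 of 12, median 2.93, or 2.15 with members at 0 in a group set to their bound) and secreted WNT inhibitors (6 of 6, median 6.69) rose, with camera adjusted p-values of 0.013, 0.0082 and 5e-04. With an estimated correlation their adjusted p-values were 0.12, 0.12 and 0.2, and Igfbp4 was the member called (1.44). The secreted WNT inhibitor score was 2.36 ± 0.83 in GFP and 1.01 ± 0.04 in mScarlet. It was 3.55 in GFP library 4, which also had the highest fibroblast score, and at least 1.69 in each GFP library. Sfrp4 was at 183 CPM in GFP library 4, at most 8.43 in the other GFP libraries and at most 0.402 in mScarlet. MHC class I genes fell (15 of 15 negative, median -0.34, camera adjusted p = 2e-04; adjusted p = 0.25 with an estimated correlation). Epithelial genes went both ways (9 of 21 positive, 12 negative). Camera called them lower (adjusted p = 0.028, 0.37 with an estimated correlation and 0.12 with the block), while their mean score was 5.48 ± 0.65 in GFP and 5.42 ± 0.16 in mScarlet. Fibroblast (20 of 20 positive, median 5.27, camera adjusted p = 1.7e-10), macrophage (20 of 20, median 3.13, camera adjusted p = 2.9e-06), acinar (20 of 21, median 4.4, camera adjusted p = 1.6e-08) and endothelial markers (14 of 14, median 2.58, camera adjusted p = 0.0022) rose beside them. Their adjusted p-values with an estimated correlation were 0.17, 0.35, 0.35 and 0.12. Adjusted over the list alone, 18 fibroblast, 14 macrophage and 19 acinar markers were called higher, against 7, 0 and 0 over all genes. Col1a1 (5.28), Col3a1 (6.32), Fbln1 (5.18) and the endothelial gene Eng (4.31) were called. The first 3 were at 1590, 5220 and 453 CPM in GFP library 4, against at most 325, 911 and 35.1 in the other GFP libraries. Eng was at 37.9 and 31.3 CPM in GFP libraries 1 and 4 and at 1.67 and 5.29 in libraries 2 and 3. Il6, called above, was at 31.1 and 28.9 CPM in GFP libraries 1 and 4 and at 3.92 and 2.39 in libraries 2 and 3.

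In all, 245 genes were called in GFP vs mScarlet, 170 higher and 75 lower, and 1190 with the library number as a block, 709 higher and 481 lower, which included all 245. With the block, camera also called erythroid markers higher (6 of 6 positive, adjusted p = 1.2e-06; 0.088 with an estimated correlation). Of the lists called, mesenchymal genes (0.0083), secreted WNT inhibitors (0.048) and fibroblast markers (0.048) held with the block and an estimated correlation by camera adjusted p. The count was 2 without GFP libraries 1 and 4 and also 2 in a fit of these 8 libraries alone, 107, 436, 524 and 71 without GFP 1, 2, 3 and 4, 6, 19 and 18 without mScarlet 1, 2 and 3, and 126, 106 and 159 without DP 1, 2 and 3.

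DP vs GFP asked what accompanies mScarlet among GFP-positive cells. Higher in DP were Clca1 (log2 fold change 3), Agr2 (2), Fam3b (1.89), Bco2 (1.84), Mfsd4a (1.51), Prap1 (1.48), the membrane protein Mal (1.44) and Tmem117 (1.41). Agr2 (chromosome 12, 35992925 to 36004081) was at 43.7 ± 23.8 CPM in DP and 10.9 ± 4.54 in GFP (SE 0.41, edgeR adjusted p = 0.0414). Lower in DP were the collagen Col15a1 (-5), the matrix protein Fbln1 (-4.85), the muscle cadherin Cdh15 (-4.22), Angptl2 (-3.33), Lgr6 (-3.26), Rps6ka2 (-3.01), Smtn (-2.68) and Eno3 (-2.53). Col15a1 and Fbln1 were at 29.5 and 453 CPM in GFP library 4, against at most 6.45 and 35.1 in the other GFP libraries. Cdh15 (chromosome 8, 122848374 to 122867397) was at 2.61 ± 2.81 against 48.7 ± 16.6 CPM (SE 0.61, edgeR adjusted p = 0.0166). Over 26 alternative settings the call of Fbln1 was kept in 7, those of Agr2, Bco2 and Clca1 in 11, that of Cdh15 in 20 and that of Eno3 in 26.

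Of the lists, 15 were called in DP vs GFP. Classical PDAC genes rose (21 of 22 positive, median 0.81, camera adjusted p = 2.5e-09; adjusted p = 0.16 with an estimated correlation), with Krt20 (1.28) and Ctse (1.22) called. Mesenchymal genes fell (15 of 18 negative, median -2.28, camera adjusted p = 8.3e-07; adjusted p = 0.0497 with an estimated correlation), with S100a4 (-2.21), Itga5 (-1.27) and Fn1 (-1.97) called. Hypoxia and glycolysis genes fell (19 of 20 negative, median -0.73, camera adjusted p = 1.9e-11; adjusted p = 0.16 with an estimated correlation), with Eno1 (-0.88) and Gpi1 (-0.71) called and 12 called adjusted over the list alone. G2/M phase (22 of 22 negative, median -1.41), DNA replication (20 of 20, median -0.72) and MYC and ribosome biogenesis genes (19 of 20, median -0.3) fell, with camera adjusted p-values of 2.3e-10, 3.1e-08 and 0.0041. With an estimated correlation their adjusted p-values were 0.18, 0.23 and 0.18, and Cdc20 (-1.49), Plk1 (-1.48) and Mcm5 (-1.24) were called. WNT/beta-catenin targets (14 of 21 negative, median -0.78), WNT ligands (11 of 12, median -1.59) and secreted WNT inhibitors (6 of 6, median -4.53) fell, with camera adjusted p-values of 0.021, 0.026 and 0.00058. Their adjusted p-values with an estimated correlation were 0.16, 0.18 and 0.18, and Apcdd1 (-3.37) and Igfbp4 (-1.64) were called. The secreted WNT inhibitor score was 1.17 ± 0.22 in DP and 2.36 ± 0.83 in GFP, with 3.55 in GFP library 4. Immediate-early and heat shock genes fell (17 of 20 negative, camera adjusted p = 0.016; adjusted p = 0.46 with an estimated correlation). MHC class I genes rose (15 of 15 positive, camera adjusted p = 0.00091; adjusted p = 0.27 with an estimated correlation). Epithelial genes went both ways (13 of 21 positive, 8 negative). Camera called them higher (adjusted p = 0.044, 0.46 with an estimated correlation and 0.092 with the block), while their mean score was 5.46 ± 0.09 in DP and 5.48 ± 0.65 in GFP. Fibroblast (19 of 20 negative, median -3.93, camera adjusted p = 2.6e-10), acinar (20 of 21, median -6.71, camera adjusted p = 2.1e-09) and endothelial markers (13 of 14, median -1.75, camera adjusted p = 0.0067) fell beside them. With an estimated correlation their adjusted p-values were 0.18, 0.3 and 0.18, and 15 fibroblast and 20 acinar markers were called lower adjusted over the list alone, against 1 and 0 over all genes.

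In all, 90 genes were called in DP vs GFP, 32 higher and 58 lower, and 813 with the library number as a block, 340 higher and 473 lower, which included all 90. With the block, camera also called NF-kB genes (16 of 22 negative, adjusted p = 0.038) and erythroid markers (6 of 6 negative, adjusted p = 6.2e-05) lower and neutrophil markers higher (11 of 15 positive, adjusted p = 0.039), with adjusted p = 0.4, 0.13 and 0.49 at an estimated correlation. Of the lists called, mesenchymal genes (0.0096), secreted WNT inhibitors (0.015), hypoxia and glycolysis genes (0.045) and fibroblast markers (0.045) held with the block and an estimated correlation by camera adjusted p. The count was 1 without GFP libraries 1 and 4, also 1 in a fit of these 8 libraries alone and without GFP 1, DP 1, DP 2 or DP 3 singly, 224, 297 and 7 without GFP 2, 3 and 4, 31 and 14 without DN 2 and 4, and 31 without mScarlet 2.

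DP vs mScarlet asked what accompanies GFP among mScarlet-positive cells. Macrophage markers were higher in DP (20 of 20 positive, median log2 fold change 2.22, camera adjusted p = 3.1e-15; adjusted p = 0.97 with an estimated correlation). Apoe was at 3170 ± 2080 CPM in DP and 467 ± 591 in mScarlet, the pan-leukocyte gene Ptprc at 6.4 ± 1.94 and 1.17 ± 0.369, and Cd68 and Ms4a7 had log2 fold changes of 1.85 and 2.52, none of them called. Fibroblast markers rose (18 of 20 positive, median 1.37, camera adjusted p = 0.031) and acinar markers fell (20 of 21 negative, median -2.3, camera adjusted p = 0.017), each with an adjusted p of 0.97 with an estimated correlation. G2/M phase (19 of 22 negative, median -0.28) and DNA replication genes (16 of 20 negative, median -0.22) fell and immediate-early and heat shock genes rose (16 of 20 positive, median 0.19), each with a camera adjusted p of 0.014 and an adjusted p of 0.97 with an estimated correlation. Tnc came nearest to the threshold among the list members (6 counts in mScarlet and 462 in DP, edgeR adjusted p = 0.102). edgeR called 0 genes, with 460 at an unadjusted p under 0.05, and also 0 with the block, while DESeq2 called 50, the fit without a filter 1 and the fit without DP library 3 also 1. With the block, camera also called NF-kB genes (18 of 22 positive, adjusted p = 0.01) and erythroid markers (6 of 6 positive, adjusted p = 0.0025) higher, with adjusted p = 0.48 and 0.32 at an estimated correlation. The count of lists called was 2 without mScarlet library 4, and likewise without DP library 2, against 6 with all libraries.

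The differences with mScarlet ran the same way with and without GFP. Of the 188 genes called in mScarlet vs DN, 187 had the same sign in DP vs GFP, which uses other libraries. In both comparisons 48 genes were called, 16 higher and 32 lower, where independent lists would share 0.154 and 0.403, and 0 were called in opposite directions. With the block it was 436 genes, 183 higher and 253 lower, against 8.56 and 13.7. The values for independent lists leave out what the comparisons share through the library numbers and the joint fit. Eno3, Rps6ka2, Smtn and Clca1 were among the named genes of both. The count was 1 without GFP libraries 1 and 4 and singly without GFP 1, DP 1, DP 2 or DP 3, 13, 14 and 6 without DN 1, 2 and 4, 91 and 6 without GFP 3 and 4, and 10, 10 and 14 without mScarlet 1, 2 and 3. For the difference with GFP (GFP vs DN and DP vs mScarlet) edgeR called 0 genes in both comparisons and DESeq2 8. With the block 11 genes were called in GFP vs DN and 0 in DP vs mScarlet, and 11 of the 11 had the same sign there.

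The interaction, whether the GFP effect differed with mScarlet, called 0 genes with edgeR (525 at an unadjusted p under 0.05) and 38 with DESeq2. As lists, acinar markers (20 of 21 negative, median -6.78, camera adjusted p = 1.9e-12), immediate-early and heat shock genes (19 of 20 negative, median -0.37, camera adjusted p = 0.00093) and NF-kB genes (19 of 22 negative, median -0.41, camera adjusted p = 0.0058) had a GFP effect that was lower in mScarlet-positive cells. For acinar markers it had the opposite sign there, at a mean score difference of -1.08 for DP minus mScarlet (0 of 4 positive) against 2.75 for GFP minus DN (7.52 for number 4, 0.17 to 2.05 for the others). For the 3 lists in this order the camera adjusted p-values with an estimated correlation were 0.85, 0.92 and 0.55. With the block camera called 6 lists, besides these 3 a lower GFP effect of erythroid markers (6 of 6 negative, adjusted p = 0.00086) and a higher one of hypoxia and glycolysis genes (17 of 20 positive, adjusted p = 0.043) and of lipid and sterol synthesis genes (15 of 20 positive, adjusted p = 0.012). At an estimated correlation these 3 had adjusted p = 0.49, 0.69 and 0.64.

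**Figure D4:**
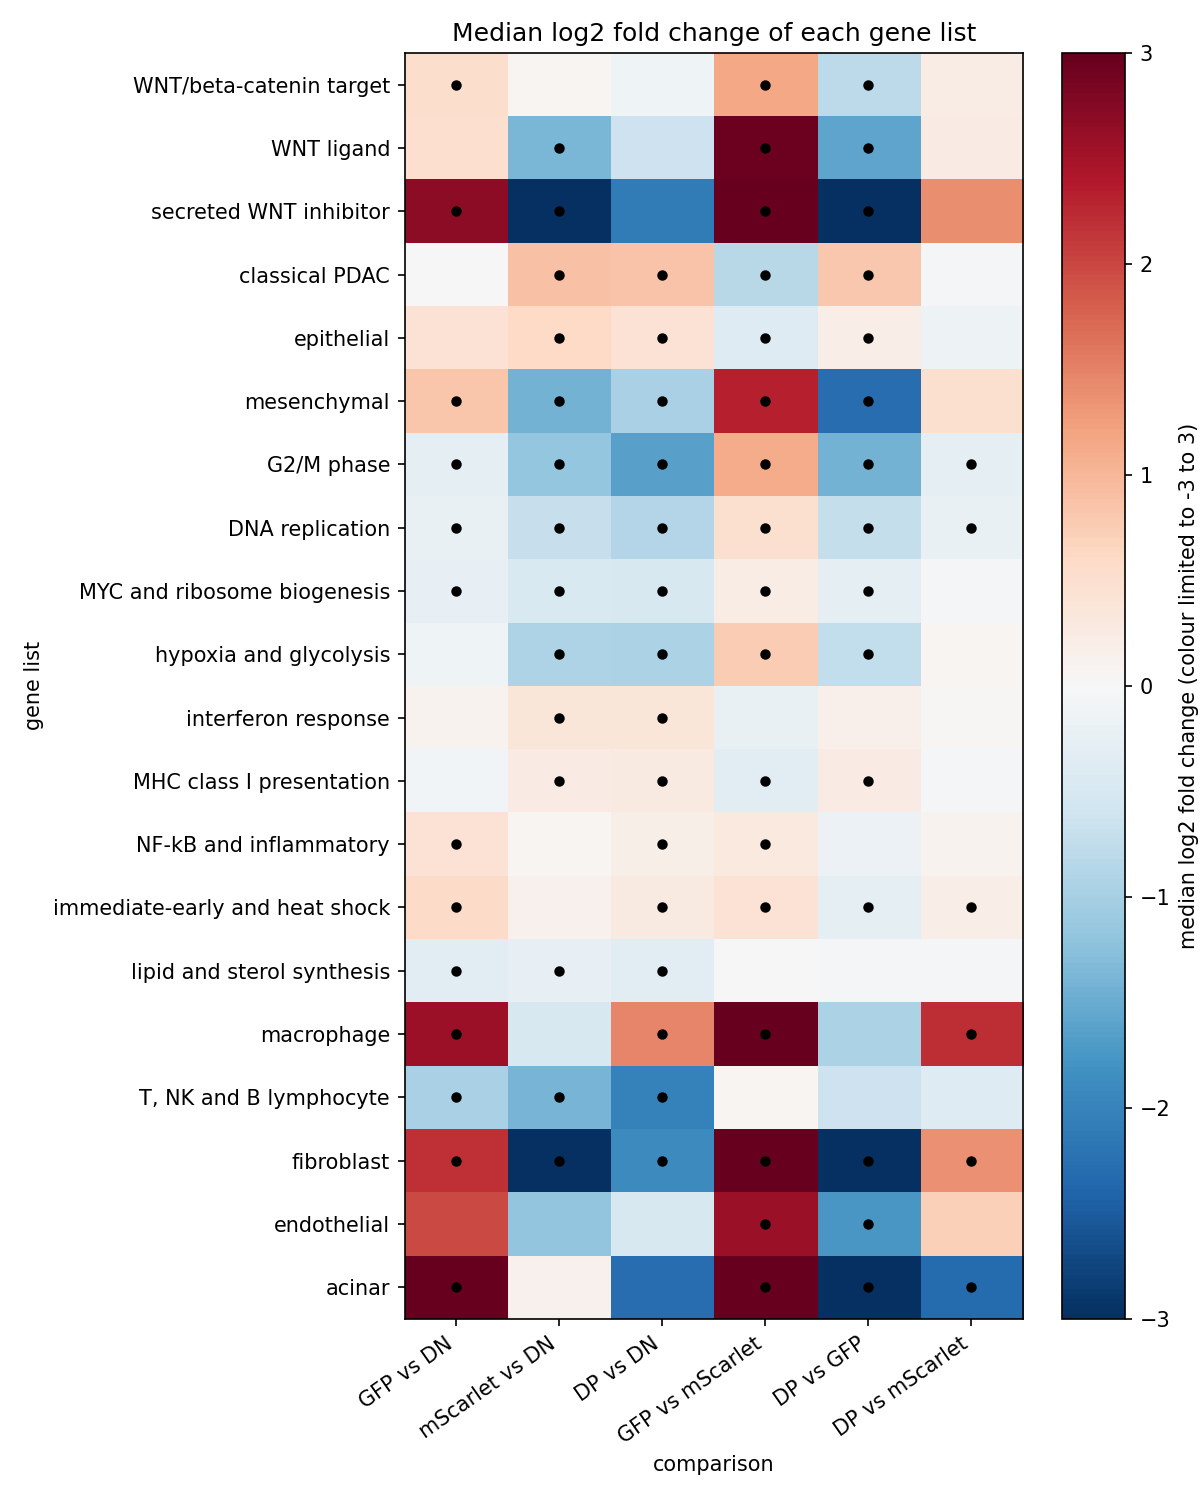
Median log2 fold change of the tested members of each gene list called in at least 1 of the 6 comparisons (vertical), by comparison (horizontal), as colour limited to -3 and 3. A dot marks a camera adjusted p under 0.05 with the preset correlation. Hypoxia and glycolysis genes had medians of -0.93 in mScarlet vs DN and -0.73 in DP vs GFP.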

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

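Of the tests below, those of GC content and transcript length were written before their result was seen, and all others after the result they bear on was seen.

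Macrophage markers were higher in both GFP-positive populations than in their GFP-negative partners, by a mean score difference of 1.7 (SE 0.54) for GFP minus DN and 1.82 (SE 0.26) for DP minus mScarlet, with 4 of 4 same-numbered differences positive in each. If the other cells kept the same mix in each gate, a smaller share of cancer cells would raise them all alike. Acinar (2.75, SE 1.64, with 7.52 for number 4), fibroblast (1.51, SE 0.39), erythroid (1.58, SE 0.94), endothelial (0.4, SE 0.36), endocrine (0.37, SE 0.2) and neutrophil markers (0.2, SE 0.29) were also higher in GFP than DN, and erythroid (0.82, SE 0.38), fibroblast (0.6, SE 0.31), neutrophil (0.23, SE 0.17), endothelial (0.18, SE 0.06), endocrine (0.04, SE 0.03) and lymphocyte markers (0.03, SE 0.06) in DP than mScarlet. Lymphocyte markers differed by -0.45 (SE 0.19) between GFP and DN and acinar markers by -1.08 (SE 0.75, with -3.33 for number 1) between DP and mScarlet, each with 0 of 4 differences positive where 4 of 4 were for macrophage markers. Both directions were known beforehand, and the mix of other cells may differ between gates, so these values do not decide against a smaller share. Macrophage cells or their RNA in the sorts, which were gated for cancer cells, may account for the pattern, but the median spread of a marker around the list mean, 0.52 times the spread of that mean, decides nothing, since a shared programme in the sorted cells would also move the markers together. Apoe, the most abundant marker named, was at 4840 ± 4980 CPM in GFP and 625 ± 635 in DN.

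The WNT target score was higher in GFP than DN by 0.33 (SE 0.08), and turned to -0.06 with only members at 5 CPM or more. With the fibroblast score as a covariate the difference was 0.25 (SE 0.08), with the acinar score 0.29 (SE 0.09) and with the macrophage score 0.37 (SE 0.09). Each lay above 0 by more than its SE, so no 1 of these scores, fitted with a common slope, took up the whole difference. The scores were not fitted together. Lgr5 had most of its GFP reads in library 1 (156 of 285 counts) and Tnfrsf19 in library 4 (676 of 1184). RNA of several cell types together stays open as the cause. So does a WNT response in the GFP gate, which the design names. DP cells also passed that gate. Their score was 1.89 ± 0.04, against 1.86 ± 0.07 in mScarlet (difference 0.035, exact permutation adjusted p = 0.4571). A clearly higher score thus accompanied GFP only in cells without mScarlet.

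Hypoxia and glycolysis genes were lower in mScarlet than DN by 0.94 on the score scale (-0.94, SE 0.21). Among 10000 random lists matched on GC content, length and level, the middle list had a median log2 fold change of 0.008 and the lowest -0.32, against -0.93 for the list, which argues against these properties as the cause. The score difference was -0.67 (SE 0.19) with the fibroblast score and -1.06 (SE 0.18) with the number of genes detected as a covariate, which argues against either as the whole cause. A difference between the sorted populations remains a hypothesis, found and tested on the same data.

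In the 4 libraries of a group, a library stood apart in 26 of 522 groups of values tested, and a rate of 5% would give 26.1. That rate holds for normal and independent values, while these come from the same 16 libraries. The measure also cannot flag 2 libraries of a group that stand apart together. The match therefore does not show that no library stands apart. The 522 leave out 7 groups with 4 libraries at 0 and 7 with 3 at 0, where the share below is 1 by construction. The latter 7 are listed with their counts. The gap to the nearest library as a share of the range was 0.893 for the glycolysis score in DP (library 4 at 7.82, the others at 6.98 to 7.07), 0.871 for the p53 score in GFP (library 3 at 4.12) and 0.869 for the endocrine score in mScarlet (library 1 at 0.018). Among WNT genes it was 0.855 for Axin2 in DN (library 1), 1 for Axin2 in mScarlet (library 4, 2 counts), 1 for Notum in mScarlet (library 3, 62 counts) and in DP (library 2, 9 counts), 1 for Sp5 in DP (library 1, 2 counts), 0.95 and 1 for Tnfrsf19 in mScarlet and DP (library 4 in both, 22 and 115 counts), 0.864 for Tcf7l1 in GFP (library 4) and 0.853 for Sfrp4 in DN (library 4). In mScarlet it was 0.853 for Lypd8 (library 1, 173 CPM), 0.836 for Ank, 0.832 for Gzme, 0.874 for Eno1, 0.89 for Gpi1 and 0.845 for Ccl7 (library 4 in all 5), 0.854 for Krt20 (library 1) and 1 for Crocc2 and Ccl19 (library 3, 1 and 2 counts). In DP it was 0.934 for Crocc2 and 0.86 for Tspan1 (library 4 in both). In GFP it was 0.871 for Ccl19, 0.9 for Cyp1b1 and 0.846 for Loxl2 (library 4), and 0.849 for Prap1 and 0.852 for Cdc45 (library 1). In DN it was 0.921 for Slco2b1, 0.889 for Mfsd4a, 0.89 for Mal and 0.913 for Uhrf1 (library 1), and 0.974 for P4ha2 (library 4).

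The difference of the GFP effect with and without mScarlet was past the threshold for 3 lists with camera without the block, NF-kB genes (adjusted p = 0.0058), immediate-early and heat shock genes (adjusted p = 0.00093) and acinar markers (adjusted p = 1.9e-12), and for none of them with an estimated correlation (adjusted p = 0.55, 0.92 and 0.85).

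Other splits of the same 8 libraries into 4 and 4 bear on whether chance can be excluded, out of 35 for each comparison. For genes, only the real split was as large in mScarlet vs DN (188 called, highest other 0) and DP vs DN (371, highest other 0). The same held in GFP vs mScarlet (245, highest other 0) and DP vs GFP (90, highest other 1). A share of 1 in 35 is the smallest possible and was not adjusted over the 6 comparisons. It also assumes libraries that are free to change places, while the numbers were taken above to pair them. Chance is therefore not excluded for these counts. For genes called the same way with mScarlet, 1 of 100 drawn splits was as large (48, highest other 0). This adds little, since other splits called 0 genes in mScarlet vs DN and at most 1 in DP vs GFP. In GFP vs mScarlet 1 split called as many gene lists (17 called, highest other 14). This share was not adjusted over the 6 comparisons, so there chance stays open. For gene lists it cannot be excluded in GFP vs DN (2 splits as large, 13 called, highest other 13) or mScarlet vs DN (4, 14 and 16). Nor can it be in DP vs DN (2, 15 and 18), DP vs GFP (2, 15 and 15) or DP vs mScarlet (15, 6 and 9). Where 0 genes were called, every split is as large by construction, which says nothing about chance. This applies to GFP vs DN (35; highest other 131), DP vs mScarlet (35; highest other 4) and, over 100 drawn splits, the interaction (100; highest other 5) and both GFP comparisons together (100; highest other 0). The split of GFP and DN that called 131 set numbers 1 and 4 against 2 and 3, which points to a structure of the samples. If the numbers pair the libraries, the real split compares with the 8 splits that part all pairs, too few for a share under 0.05. Among these the highest other split called 0 genes in each comparison, and 13, 13, 14, 14, 12 and 4 lists in GFP vs DN, mScarlet vs DN, DP vs DN, GFP vs mScarlet, DP vs GFP and DP vs mScarlet, against 13, 14, 15, 17, 15 and 6. In the splits parting no pair, the highest count of genes was 131 in GFP vs DN, 4 in DP vs mScarlet and 0 in the others.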

How the results depend on the processing

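The fit without GFP libraries 1 and 4 was chosen after seeing the data, and all other alternatives before. Counts of genes are given in the order GFP vs DN, mScarlet vs DN, DP vs DN, GFP vs mScarlet and DP vs GFP (0, 188, 371, 245 and 90 as reported), and the cause of each change was not tested unless named. DESeq2 called 245, 808, 1020, 1518 and 1010, and limma voom with quality weights 2, 787, 914, 112 and 46. The fit with the replicate number as a block called 11, 865, 1017, 1190 and 813. With the number of genes detected as a covariate the last 4 were 847, 717, 1043 and 323, and with that covariate and the block 1 in GFP vs DN, 565 in DP vs DN, 953 in GFP vs mScarlet and 642 in DP vs GFP. The 8 libraries of a comparison alone gave 343, 578, 2 and 1 in the last 4, and the fit without GFP libraries 1 and 4 gave 580, 761, 2 and 1. The stricter filter, which tests fewer genes, gave 312 in mScarlet vs DN and 259 in DP vs GFP, no filter 141 in GFP vs mScarlet, and RLE size factors 137 in DP vs GFP. For DP vs mScarlet no filter called 1 and DESeq2 50, and for the interaction DESeq2 called 38. Genes called the same way were 8 with GFP under DESeq2, and with mScarlet (48 as reported) 131 under the stricter filter, 368 under DESeq2, 436 with the block, 225 with genes detected, 194 with genes detected and the block, and 1 without GFP libraries 1 and 4.

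Gene lists called with an estimated correlation were 1, 0, 0, 1, 1 and 0, and with fry 1, 8, 9, 9, 8 and 0, in the order GFP vs DN, mScarlet vs DN, DP vs DN, GFP vs mScarlet, DP vs GFP and DP vs mScarlet (13, 14, 15, 17, 15 and 6 as reported), and DP vs mScarlet had 2 with genes detected as a covariate. Leaving out 1 library at a time gave ranges of 0 to 2, 17 to 362, 105 to 532, 6 to 524, 1 to 297 and 0 to 1 genes and of 9 to 15, 9 to 15, 10 to 18, 14 to 18, 12 to 17 and 2 to 8 lists in that order, of 0 to 0 genes for the interaction and for both GFP comparisons together, and of 1 to 91 for both mScarlet comparisons together. The WNT target score ranged from 0.271 to 0.384, -0.135 to -0.047, -0.101 to -0.012, 0.363 to 0.481, -0.446 to -0.332 and 0.005 to 0.059. A block on the number cannot change these score differences, since each group holds every number. Taken as pairs, they had exact permutation adjusted p-values of 0.25, 0.375, 0.5, 0.25, 0.25 and 0.45. With the block the interaction and DP vs mScarlet stayed at 0 genes. The block changed no other call of a list, or of a gene in a comparison for which it is named, than those given with the results. Same-numbered libraries correlated in all comparisons, with 2 to 4 of 4 pairs above 0.1, and 10 of 16 libraries correlated best with their own number in all other groups. RLE size factors shifted the median gene by at most 0.037 upward and -0.039 downward in log2.

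Some values turned their direction, and the cause was not tested. With only members at 5 CPM or more the WNT target score differences became -0.06 in GFP vs DN, 0.011 in DP vs DN, -0.036 in GFP vs mScarlet and 0.071 in DP vs GFP. Macrophage markers, lower in DP than GFP without passing (camera adjusted p = 0.83), passed as higher without GFP library 1 (0.004) and as lower without GFP library 4 (0.0025), and leaving out 1 library gave adjusted p-values from 0.0025 to 0.92. The others are log2 fold changes of genes not called. Axin2, which had few reads, went from 1.65 in GFP vs DN to -0.85 with limma voom, -0.68 with the replicate block, 0 with genes detected, -0.67 with both and -3.26 without GFP libraries 1 and 4 (-0.87 to 3.1 leaving out 1 library). It went from 0.87 in DP vs DN to -0.51, -1.22, -1.33 and -1.2 in the first 4 of these. For Axin2, DP vs GFP, -0.78 became 0.35 with limma voom and 4.12 without GFP libraries 1 and 4 (-1.53 to 1.73 leaving out 1 library). Lef1 went from -0.41 in GFP vs DN to 0.14 with limma voom, 0.16 with genes detected and the block and 0.57 without GFP libraries 1 and 4 (-1.62 to 0.07), from 0.45 in mScarlet vs DN to a range of -0.37 to 0.93, and from -0.86 in GFP vs mScarlet to 0.13 without GFP libraries 1 and 4. Wls went from 0.06 in mScarlet vs DN to -0.09 with limma voom (-0.1 to 0.17), and ranged from -0.04 to 0.23 in GFP vs DN and -0.07 to 0.19 in GFP vs mScarlet, and Porcn from -0.09 to 0.22 in GFP vs DN. Without GFP libraries 1 and 4, Dkk3 (-0.1), Fn1 (0) and Fbln1 (-0.06, and -0.08 to 2.71 leaving out 1 library) in GFP vs DN, Cldn3 in GFP vs mScarlet (-0.12) and Cldn7 in DP vs GFP (4.79) turned as well.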

Other observations

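Among the gene lists not called with camera in any of the 6 comparisons without the block were WNT secretion machinery, WNT receptors, basal-like PDAC, TGF-beta targets, YAP/TAZ targets, Notch targets, the unfolded protein response, p53 targets, and neutrophil, endocrine and erythroid markers. No called list had a median and a camera direction of opposite sign, and the mean score went against camera for epithelial genes in GFP vs mScarlet and DP vs GFP. Among lists not called, secreted WNT inhibitors in DP vs mScarlet had a median log2 fold change of 1.39 with camera pointing down, and macrophage markers in mScarlet vs DN had -0.48 with camera pointing up. Epcam, an epithelial surface marker chosen after its values were seen, was at 29.4 CPM in GFP library 4 and at no more than 0.476 CPM in any other library.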
